A study of Mus musculus with 17 samples.

How the data were processed

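Gene expression was measured in 16 bulk libraries and 1 single-cell library of mouse innate lymphoid cells. Of the bulk libraries, 8 came from lymphoid tissue inducer (LTi) cells of the colon lamina propria. They had been sorted as live, lineage-negative, CD127-positive, KLRG-1-negative, c-Kit-positive and CCR6-positive cells, and then by surface human PD-1. The mice, Pdcd1hu/+ or Pdcd1hu/-, had received 3% dextran sulfate sodium (DSS) in the drinking water for 6 days and plain water for 1 day. The sample titles call Pdcd1hu/+ cells WT and Pdcd1hu/- cells KO. Of the others, 4 came from small intestinal LTi cells of Pdcd1-/-Rag2-/- mice cultured with palmitic acid and L-carnitine, with etomoxir or its vehicle water. Etomoxir was given at 60 µM for 2 days and at 200 µM for the next 2 days. The last 4 came from small intestinal LTi cells of B6 mice cultured for 3 days with or without palmitic acid, at a concentration printed as 100 mM in the labels. The single-cell library held small intestinal cells sorted as live, lineage-negative and CD127-positive.

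The bulk values were read counts per gene, which the authors made with HISAT2 2.1.0 and featureCounts, per the submitters' processing notes. Per the labels' protocols, cDNA was made with the SMART-Seq HT kit, libraries with the NEBNext Ultra DNA kit, and reads were paired with 150 bases. The notes named the mm10 build for the colonic and etomoxir libraries, and mm10 together with GRCm39 for the later samples. Per the file headers of both libraries with palmitic acid, featureCounts 2.0.3 had been run in its paired mode on the Ensembl annotation of GRCm38, so coordinates are those of that build. Per the file headers, the count columns of these libraries are named iL where the labels say P, and those without palmitic acid iC where the labels say C, so the assignment rests on the file names and labels alone. In the deposited counts of the palmitic acid experiment, between 59.96% and 61.07% of the values from 1 to 20 were even, against 36.19% to 43.97% elsewhere. Both mates of a pair appear to have been counted there, so its counts overstate the number of fragments. No strand option was given, so overlapping genes on opposite strands share reads. The colonic tables held 55573 genes and the others 54446. Of the colonic genes, 54353 took their symbol from the palmitic acid tables and 1041 from the reference annotation, while 179 had none. No column belonged to a sample outside the series.

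The single-cell values were molecule counts (UMI counts) per gene and cell from a BD Rhapsody run, per the labels' protocols. The deposited table held 18099 gene symbols and 8219 barcodes with no cell annotation. The counting software, the cell filter and the build were not given in the sources used here.

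Total counts per bulk library ran from 14556247 to 28992085. A floor of 3 counts corresponded to between 0.103 and 0.206 CPM. The single-cell table held 22835963 UMIs, with a median of 2698 per cell.

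The comparisons followed the labels and were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust) in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. All 8 colonic libraries entered 1 fit with 4 group means, which left 4 residual degrees of freedom. The contrasts were PD-1high against PD-1neg cells in each genotype, their average, the genotypes within each gate, and the interaction. The etomoxir and the palmitic acid libraries were fitted apart, since mice, tissue and annotation differed. Printed CPM values are TMM-scaled unless stated otherwise. Fold changes are on the log2 scale with their standard error (SE). Where a group was at 0, the fold was computed against 3 counts over that group.

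The vehicle libraries of the etomoxir experiment were summed into 1 sample, which departs from the planned fit with 2 vehicle samples. Per the file headers, both vehicle columns carry the same alignment name. Between them, the chi-square per degree of freedom over 14021 genes was 2.22, the correlation of log2 values was 0.992, and no gene at 20 counts or more in either was at 0 in the other. In the remaining 7 groups the chi-square per degree of freedom lay between 24.9 and 372, and the correlation between 0.493 and 0.921. The etomoxir fit therefore had 1 residual degree of freedom. The labels do not say whether replicates were separate mice, cultures or aliquots, so they may be technical.

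Gene lists, 32 in number, had been written down before the data were examined. Each list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. These p-values were adjusted over the lists within a comparison. Every camera call was recomputed with an estimated correlation and with fry. Both rest on the residual degrees of freedom of the fit, 4 for the colonic libraries, 2 for palmitic acid and 1 for etomoxir. So few may leave these tests little room to call any list, but their power was not simulated. A call lost there therefore leaves the list undecided. Members were counted as higher or lower by their adjusted p over all genes, and again adjusted over the list alone.

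Genes were named by a rule fixed beforehand. It always names Pdcd1, Kit, Ccr6, Il7r, Cpt1a, Il22 and Il17a, and some genes it names are not reported here. It adds the 6 largest increases and the 6 largest decreases past the threshold, with an average log2 CPM of at least 4 and no overlap between the groups. Where fewer than 6 pass, the smallest unadjusted p-values fill up to 3 names per direction, given as not past the threshold. Gene models without a proper symbol, pseudogenes and small RNAs are left out. From each list with a set test past the threshold, the 3 members with the smallest unadjusted p are named, and always from the lists of effector cytokines, early response, fatty acid oxidation and glycolysis. From lists of other cell types or RNA quality, the member with the highest mean is named.

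Single cells were kept with at least 200 genes and under 20% mitochondrial UMIs, which all 8219 barcodes passed. Scrublet at an expected doublet rate of 0.05 called 135 cells (1.64%) as doublets, and these were left out. Scanpy 1.11.5 was used with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1. A cluster was called after a class when at least 3 of the class's markers were detected in at least 5% of its cells and were higher than in the other cells. Further conditions were set after a first clustering had been looked at: the markers had to be at least 1.5-fold higher and to make up at least 40% of the class's markers, the class with the best share won, and markers shared by all ILC3 gave no name. They left cluster 5 without a name. With 1 sample there was no test. Summed UMIs carry exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals, at a confidence level of 95%. A gene counted as different between classes when the intervals did not overlap and the ratio was at least 2-fold. Levels of Cd74, H2-Aa, Vegfa and the uncoupling proteins lie outside the naming rule and were chosen after they had been seen. For shares of cells and for relations between lists, cells were thinned to 1500 UMIs. Relations were ranked among 1000 random lists matched on mean expression.

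The fits were tested on simulated counts with 200 changed genes among the real ones. These were drawn from genes with a mean above 10 CPM, so recovery of weaker genes was not tested. Of the genes changed 4-fold, 4% were recovered for the gates in Pdcd1hu/+, 38% for the gates averaged over genotypes, 74% for etomoxir and 96% for palmitic acid. Of the genes changed 16-fold, the shares were 48%, 78%, 100% and 100%, and of those changed 2-fold 0%, 0%, 24% and 68%. For the palmitic acid libraries, a planted list of 30 genes raised 2-fold reached a camera p of 1.67e-29, and 0 of 100 random lists fell under 0.05. Genes were drawn independently there, and no list was planted in colonic libraries. The result therefore says nothing about false list calls where genes vary together. Planted cell classes were recovered with an adjusted Rand index of 1.

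Alternatives were DESeq2 1.42.0, limma-voom, other scalings, no filter and a mean CPM of at least 10, a replicate block, leaving out each library, and other clustering settings. Chosen after the data had been examined were the vehicle sum, a Jchain covariate, the fit without the 4 libraries richest in Igkc, the crossed block, and the repeats of the fold-change correlations under other filters and scaling. GC content and transcript length came from the longest GENCODE M21 transcript of each gene, and near-identical copies from minimap2 2.31 at 95% identity over at least 200 bases. For each gene lower with palmitic acid, the 10 genes of 16 CPM or more nearest in GC content of the transcript and of its first 200 bases were taken as genes of like GC content, called genes included. This test replaced a subtraction of GC trends, also chosen after the result, which had almost no trend to remove (Spearman rho 0.033 and 0.01). A test in the 4 libraries with least Igkc was added after the Jchain covariate had left plasma cell RNA undecided, with a bound of -0.1 on the median in place of -0.3. The verdict on plasma cell RNA rests on the added test. After the early response list had been singled out, each split of the colonic libraries was also ranked by the smallest camera p of any list. Raw reads were not used here.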

Results

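The data comprised 16 bulk RNA libraries of sorted LTi cells, which are group 3 innate lymphoid cells, and 1 single-cell library of small intestinal innate lymphoid cells. The colonic LTi cells formed 4 groups of 2 libraries: PD-1high and PD-1neg cells from Pdcd1hu/+ mice and from Pdcd1hu/- mice, all given DSS for 6 days and water for 1 day. Total counts were 22290026 and 21967832 for Pdcd1hu/+ PD-1high, 19996378 and 16979287 for Pdcd1hu/+ PD-1neg, 16514805 and 20115499 for Pdcd1hu/- PD-1high, and 19780909 and 16479396 for Pdcd1hu/- PD-1neg. The cultured small intestinal cells formed 4 more groups of 2. Their totals were 19630851 and 15723796 with vehicle, 15535721 and 14556247 with etomoxir, 26869203 and 28717856 without palmitic acid, and 28992085 and 27888473 with it. The vehicle libraries of the etomoxir experiment differed by little more than sampling noise and were counted as 1 sample. Intervals of UMI counts and of shares given below, and floors, cover counting error only. Intervals of median fold changes come from 2000 resamples of the genes. They show the spread between genes, not between samples.

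The colonic cells were sorted by surface human PD-1, and the gene counted here is the mouse gene for PD-1, Pdcd1. The gene (ENSMUSG00000026285, protein coding) lies on chromosome 1, from 94038305 to 94052553 in GRCm38. It stood at 248 and 390 CPM in the Pdcd1hu/+ PD-1high libraries and at 8.02 and 25.4 CPM in the Pdcd1hu/+ PD-1neg libraries. In Pdcd1hu/- mice, PD-1high cells had 527 and 540 CPM and PD-1neg cells 81.9 and 188 CPM. All 4 PD-1high libraries thus lay above all 4 PD-1neg libraries. The cultured libraries labelled Pdcd1-/-Rag2-/- had 81.0 and 74.5 CPM of Pdcd1 with vehicle and 192 and 265 CPM with etomoxir, next to 81.4 to 127 CPM in the libraries of B6 mice. The labels do not state which part of the gene was deleted or replaced, so counts over the whole gene check neither genotype. For the same reason they do not measure the sorted human receptor itself.

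**Figure D1:**
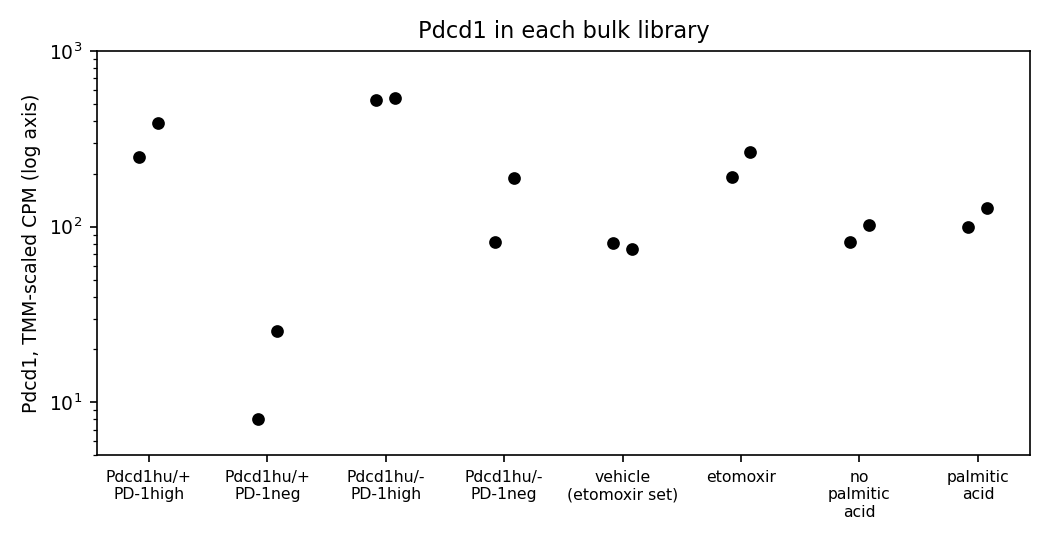
The vertical axis gives TMM-scaled CPM of Pdcd1 on a log scale, and each point is 1 of the 16 bulk libraries, placed by group. PD-1high libraries lie between 248 and 540 CPM, and PD-1neg libraries between 8.02 and 188 CPM.

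The plasma cell transcript Igkc followed neither gate nor genotype in the colonic libraries. It took 53300 and 215 CPM of the library total in Pdcd1hu/+ PD-1high, 249 and 12200 in Pdcd1hu/+ PD-1neg, 172 and 41800 in Pdcd1hu/- PD-1high, and 27200 and 129 in Pdcd1hu/- PD-1neg. The colonic groups had 15938 to 17424 genes with 20 counts or more over both replicates together. Between 2091 and 3322 of them were at 0 in one replicate and at 20 or more in the other, against 431 and 473 in the palmitic acid groups.

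The series asked which genes distinguish PD-1high from PD-1neg LTi cells. In Pdcd1hu/+ mice, the messages of early response genes, which are induced within minutes to hours of activation, were lower as a list in PD-1high cells with camera. This call was lost with an estimated correlation (adjusted p = 0.978), and no single gene passed the threshold. Effector cytokine, fatty acid oxidation and glycolysis lists did not pass either. Of 18862 genes, edgeR called 0 at an adjusted p under 0.05 and 594 at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 called 120, with 60 in each direction. The smallest edgeR adjusted p was 0.36, shared by Pdcd1 (log2 fold change 4.26, SE 0.62), Palld (2.88, SE 0.44) and Thbs2. Thbs2, which encodes the matrix protein thrombospondin-2, had 42.2 and 55.1 CPM in PD-1high cells against 0 and 0.117 CPM. The decreases with the smallest unadjusted p were Zfp36 (-1.58), Atf3 (-1.78) and Cwc25 (-2.14), which did not pass (edgeR adjusted p = 0.893).

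The early response list fell between the gates in Pdcd1hu/+ cells (camera adjusted p = 0.0114, and adjusted p = 0.978 with an estimated correlation). Its median log2 fold change was -0.85, 3 of 25 members lay above 0, and 2 were lower when adjusted over the list alone. Of 12 heat-shock genes, 1 lay above 0 in the same comparison (camera adjusted p = 0.256), and the list took 0.284% and 0.368% of counts in PD-1high against 0.568% and 0.495% in PD-1neg libraries. Fos, at 1610 and 1870 CPM against 5450 and 3170 CPM, and Dusp1, at 987 and 965 CPM against 2580 and 1930 CPM, were among its members with the smallest p. Among effector cytokines, Il22 had 39800 and 7320 CPM in PD-1high cells against 10100 and 2730 CPM. Il17f was 1.97 and Il10 7.05 higher on the log2 scale, neither past the threshold. Fatty acid oxidation members (Hadh, Hsd17b4, Acaa2) and glycolysis members (Hk2, Pfkfb3, Pfkl) went both ways. Kit, Ccr6, Il7r, Cpt1a and Il17a did not pass, with edgeR adjusted p between 0.893 and 1. Leaving out Pdcd1hu/+ PD-1neg replicate 2 gave 449 calls in place of 0, and leaving out replicate 1 of that group gave 38.

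In Pdcd1hu/- mice, the early response list was again lower in PD-1high than in PD-1neg cells with camera. Cell cycle, MHC class II and ILC2 marker lists were lower too, and mitochondrially encoded and erythroid lists higher. With an estimated correlation none of these calls held (adjusted p = 0.795 for early response and ILC2 markers, 0.959 or 0.971 for the others), the early response call also ended with a replicate block (0.0635), and no gene passed the threshold singly. edgeR called 0 genes (827 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 203, of which 66 were higher and 137 lower. The 3 increases with the smallest unadjusted p were Palld (2.65, SE 0.43), Lilr4b (2.02, SE 0.34) and Gpr35 (3.19, SE 0.61). The 3 decreases were Cd7 (-2.44, SE 0.43), Nop56 (-2.66, SE 0.52) and Acaa2 (-2.31, SE 0.44), all with an edgeR adjusted p of 0.862. Pdcd1 itself was 1.98 higher (SE 0.56, edgeR adjusted p = 0.862).

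The cell cycle list fell in Pdcd1hu/- PD-1high cells (camera adjusted p = 0.000363, and adjusted p = 0.959 with an estimated correlation), with 2 of 35 members above 0. Its low level was set against 1 library above all, since Top2a had 0.646 and 2.94 CPM in PD-1high cells against 79.3 and 7.77 CPM in PD-1neg cells. Mcm7 and Rrm1 had the same order. ILC2 markers fell (camera adjusted p = 0.012, adjusted p = 0.795 with an estimated correlation), with Areg at 59.0 and 157 CPM against 306 and 19.0 CPM. MHC class II genes fell (camera adjusted p = 0.0203, adjusted p = 0.959 with an estimated correlation), led by Ciita, H2-Oa and H2-DMa. The early response list fell (camera adjusted p = 0.0383, adjusted p = 0.795 with an estimated correlation, and 0.0635 with a replicate block). Of its members, 2 were lower when adjusted over the list alone, and Atf3, Myc and Dusp1 had the smallest p. Of 12 heat-shock genes, 0 lay above 0 (camera adjusted p = 0.088). Mitochondrially encoded messages rose as a list (camera adjusted p = 0.0203, adjusted p = 0.971 with an estimated correlation), with all 13 members above 0 and mt-Nd2, mt-Co2 and mt-Co3 named by the rule. Erythroid markers rose (camera adjusted p = 0.00725, adjusted p = 0.959 with an estimated correlation), with Hba-a1 at 2230 and 1710 CPM against 23.8 and 2.98 CPM.

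Further members named by the rule in this comparison did not pass. They were Il2 (-4.65), Tnfsf11 (0.77) and Il10 among cytokines, Acaa1a (-1.93) and Crat (4.75) in fatty acid oxidation, and Eno1 (-1.15), Gpi1 (-1.10) and Pgam1 (-1.35) in glycolysis. The glycolysis list missed the threshold under the main scaling (camera adjusted p = 0.0564) and passed with library totals alone (0.04). Il22, Il17a, Ccr6, Kit, Il7r and Cpt1a had edgeR adjusted p between 0.863 and 1. Leaving out Pdcd1hu/- PD-1neg replicate 1 gave 19 calls in place of 0.

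Averaged over both genotypes, 4 libraries stood against 4, and Palld was higher in PD-1high cells. Palld encodes palladin, an actin-associated protein of the cytoskeleton. With camera, early response, heat-shock, glycolysis, TCA cycle, cell cycle and MHC class II lists were lower, while respiratory chain lists of nuclear and mitochondrial genes and stromal and erythroid markers were higher. None of these 10 calls held with an estimated correlation (adjusted p between 0.526 and 0.968) or with fry, and those of glycolysis, the TCA cycle and the nuclear respiratory chain also ended with a replicate block. Each of the 34 other splits of the 8 libraries into 4 and 4 gave camera calls too, for 1 to 13 lists. Palld was the 1 gene called by edgeR, and limma-voom also called 1. DESeq2 called 301 genes, of which 113 were higher and 188 lower, and 1432 genes had an unadjusted p under 0.05 with edgeR. Palld (ENSMUSG00000058056, protein coding, chromosome 8, 61511433 to 61902690) rose by 2.77 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0442). PD-1high libraries had 613 ± 191 CPM (SD, n = 4) and PD-1neg libraries 90.0 ± 19.5 CPM. The call ended with a mean CPM filter of 10 (2.78, edgeR adjusted p = 0.172), a Jchain covariate (2.79, 0.16) and without the 4 libraries richest in Igkc (2.49, 0.0691), at folds close to the 2.77 above. Library totals alone moved the median of all genes by -0.11 on the log2 scale, and Palld stayed past the threshold (2.63, edgeR adjusted p = 0.0461).

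Next in order were Pdcd1 (3.12, SE 0.42, edgeR adjusted p = 0.124) and Lilr4b (1.59, SE 0.24, 0.238). The decreases nearest to the threshold were Atf3 (-1.82, SE 0.30, 0.277), Cd7 (-1.62, SE 0.29, 0.333) and Tuba4a (-1.36, SE 0.27, 0.383). Il22 was 1.30 higher with overlapping libraries (SE 0.71, edgeR adjusted p = 0.716), and Cpt1a differed by 0.08 (SE 0.44, edgeR adjusted p = 1). Kit, Ccr6, Il7r and Il17a did not pass, with edgeR adjusted p between 0.741 and 0.916.

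The early response list fell in the averaged comparison (camera adjusted p = 0.00289, and adjusted p = 0.526 with an estimated correlation). Of its 25 members, 4 lay above 0 and 5 were lower when adjusted over the list alone, with Atf3, Myc and Dusp1 leading. Heat-shock genes, which dissociation of tissue induces, fell as a list (camera adjusted p = 0.0317, adjusted p = 0.526 with an estimated correlation), with 0 of 12 members above 0. Of these, 3 were lower when adjusted over the list alone, and Hspa8, the most abundant, had 1070 ± 141 CPM against 1700 ± 301 CPM (SD, n = 4). The heat-shock list took 0.284% to 0.368% of the counts in PD-1high libraries and 0.495% to 0.684% in PD-1neg libraries.

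**Figure D2:**
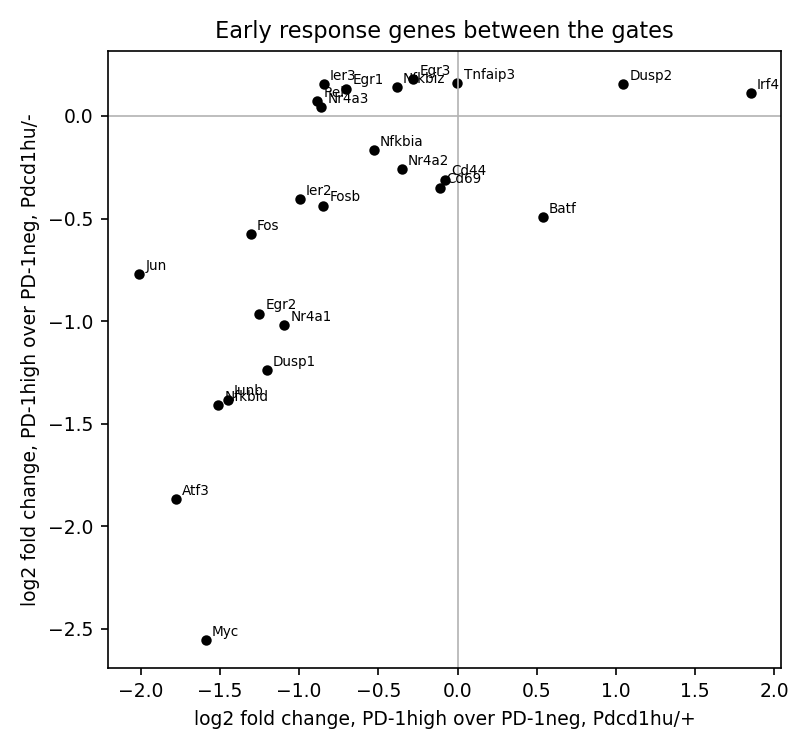
Each point is 1 of the 25 members of the early response list, with its log2 fold change of PD-1high over PD-1neg cells in Pdcd1hu/+ mice on the horizontal axis and in Pdcd1hu/- mice on the vertical axis. In Pdcd1hu/+ mice 3 members lie above 0 and in Pdcd1hu/- mice 9, and Atf3 lies at -1.78 and -1.87.

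With camera, metabolic lists went in different directions between the averaged gates, and no difference between lists was tested. Glycolysis fell (camera adjusted p = 0.0443, adjusted p = 0.968 with an estimated correlation, and 0.0803 with a replicate block), with Hk2 (-1.22) and Eno1 (-0.83) lower and Pfkfb3 (0.95) higher. The TCA cycle fell (camera adjusted p = 0.0443, adjusted p = 0.526 with an estimated correlation, 0.0803 with a replicate block), with Idh2 (-2.93) and Idh3a among its members of smallest p. Nuclear-encoded respiratory chain genes rose as a list (camera adjusted p = 0.0443, adjusted p = 0.968 with an estimated correlation), with 34 of 47 members above 0. That call ended with a replicate block (0.119) and with library totals alone (0.161), and Cox6c (0.80), Ndufa1 (1.00) and Cox7a2 (0.83) led it. Mitochondrially encoded messages rose as a list (camera adjusted p = 0.0196, adjusted p = 0.968 with an estimated correlation), with 12 of 13 members above 0. They took 6.6% and 2.06% of counts in Pdcd1hu/+ and 4.67% and 1.91% in Pdcd1hu/- PD-1high libraries, against 3.24% and 2.37% and against 2.73% and 1.21% in PD-1neg libraries, so the gates overlapped. Fatty acid oxidation did not pass (camera adjusted p = 0.405), although Acaa2 (-1.48) was 1 member lower when adjusted over the list alone, with Acaa1a (-1.22) and Crat (2.68) next.

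The MHC class II list fell between the averaged gates (camera adjusted p = 0.0387, adjusted p = 0.968 with an estimated correlation), with H2-Oa, H2-DMa and H2-Ab1 named. Its share of counts was 0.284% to 0.438% in PD-1high libraries, and 1.16%, 0.269%, 0.408% and 0.794% in PD-1neg libraries. Cell cycle genes fell (camera adjusted p = 0.0472, adjusted p = 0.968 with an estimated correlation, 0.0866 with library totals alone), among them Ccna2, Ccnb1 and Mcm7, of which 1 library, Pdcd1hu/- PD-1neg replicate 1, held most. Stromal markers rose (camera adjusted p = 0.0196, adjusted p = 0.968 with an estimated correlation), with Dcn at 4.56 to 1100 CPM over all 8 libraries and the largest share of the list in a PD-1neg library (0.43%). Erythroid markers rose (camera adjusted p = 0.0146, adjusted p = 0.968 with an estimated correlation), with Hba-a1 at 19.9 to 3600 CPM in PD-1high and 2.98 to 366 CPM in PD-1neg cells. In Pdcd1hu/+ PD-1high replicate 1 the list summed to 37.2 CPM, below both Pdcd1hu/+ PD-1neg libraries (43.4 and 739 CPM). Effector cytokines did not pass (camera adjusted p = 0.947), and the mean of that list was above 0 (0.04) while its median was below (-0.43). Il2 (-2.98), Tnfsf11 (0.70) and Il10 had the smallest p there. Leaving out Pdcd1hu/+ PD-1neg replicate 2 gave 595 calls in place of 1.

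A further question was whether the second Pdcd1 allele changes the cells that carry the receptor. It sets Pdcd1hu/- cells, titled KO, against Pdcd1hu/+ cells, titled WT. Between PD-1high cells of the genotypes, the myeloid marker list was lower in Pdcd1hu/- mice with camera (adjusted p = 0.996 with an estimated correlation), and no gene passed. edgeR called 0 genes (362 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 100, of which 29 were higher and 71 lower. The smallest unadjusted p were those of Gnptab (2.08), Scaper (2.1) and Cdc27 (1.65) upward and of Tnfsf9 (-2.73), Skap2 (-2.18) and Lum downward, each with an edgeR adjusted p of 1. Lum, a fibroblast transcript, had 0.117 and 0.0545 CPM against 153 and 31.9 CPM. Myeloid markers fell as a list (camera adjusted p = 4.26e-05, adjusted p = 0.996 with an estimated correlation), with 0 of 23 members above 0, at 0.475% and 0.44% of counts against 0.556% and 1.3%, so that Pdcd1hu/+ PD-1high replicate 2 stood apart. Fcer1g overlapped, at 2040 and 3560 CPM against 3900 and 2690 CPM. In the small intestinal single cells, Fcer1g made up 72.9% of this list in LTi-like cells, so it does not mark myeloid cells alone. Pdcd1 differed by 0.74 (SE 0.55, edgeR adjusted p = 1). Il22 was at 8450 and 11700 CPM against 39800 and 7320 CPM, and Cpt1a, Kit, Ccr6, Il7r and Il17a had an edgeR adjusted p of 1. Named members of the early response (Fos, Cd44, Nfkbia), cytokine (Il10, Ifng, Il17f), fatty acid oxidation (Acat1, Acaa2, Ech1) and glycolysis (Slc2a3, Pfkl, Gpi1) lists had an edgeR adjusted p of 1 too.

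PD-1neg cells, sorted as without surface human PD-1, served as the comparison, although their libraries still held Pdcd1 counts. There, Pdcd1hu/- cells had a higher cell cycle list and lower myeloid, interferon-stimulated and epithelial lists than Pdcd1hu/+ cells with camera, and 0 of these calls held with an estimated correlation (adjusted p = 0.859). The cell cycle list took 0.301% of counts in Pdcd1hu/- PD-1neg replicate 1 and 0.0356% to 0.0403% in the other PD-1neg libraries, and the epithelial list 0.611% in Pdcd1hu/+ replicate 2 and at most 0.0378% in the others. edgeR called 0 genes (617 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 156, of which 61 were higher and 95 lower. Pdcd1 was 3.02 higher (SE 0.59, edgeR adjusted p = 0.903), and Thbs2 had 13.7 and 8.95 CPM against 0 and 0.117 CPM. Rrm1 (2.92, SE 0.60) was the third of the increases with the smallest p. Lilr4b (-1.81, SE 0.34), Akap11 (-2.95, SE 0.66) and Cdc27 (-1.93, SE 0.47) were the decreases, none past the threshold (edgeR adjusted p = 0.903). Cell cycle genes rose as a list (camera adjusted p = 1.21e-06, adjusted p = 0.859 with an estimated correlation), with 34 of 35 members above 0, and 1 was higher when adjusted over the list alone. Uhrf1 had 82.8 and 7.43 CPM against 3.22 and 0.409 CPM, and Cenpf 39.0 and 0 CPM against 0 in both. Myeloid markers fell (camera adjusted p = 8.18e-05, adjusted p = 0.859 with an estimated correlation), at 0.555% and 0.221% of counts against 0.522% and 1.17%, so that Pdcd1hu/+ PD-1neg replicate 2 stood apart.

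Interferon-stimulated genes fell in PD-1neg cells of Pdcd1hu/- mice (camera adjusted p = 0.022, adjusted p = 0.859 with an estimated correlation). Cmpk2 was at 0 in both libraries, at least 139-fold below the Pdcd1hu/+ libraries, and Oas2 at least 72.8-fold below, with Rsad2 next. As a share of counts the list was not lower in both replicates, at 0.081% and 0.123% against 0.0714% and 0.124%. Epithelial markers fell (camera adjusted p = 0.0393, adjusted p = 0.859 with an estimated correlation), and Krt8 had 1.17 and 0.113 CPM against 2.16 and 2000 CPM, so that 1 library held nearly all of it. The cytokine list had a median above 0 (0.37), a mean below 0 (-0.62) and a camera direction upward (adjusted p = 0.745). Named members that did not pass were Il2, Ifng and Il10 among cytokines, Nfkbia, Nfkbiz and Rel in the early response, Etfdh, Acaa2 and Crat in fatty acid oxidation, and Pgam1, Tpi1 and Slc16a1 in glycolysis. Kit, Ccr6, Il7r, Cpt1a, Il22 and Il17a had edgeR adjusted p between 0.995 and 1. Leaving out Pdcd1hu/+ PD-1neg replicate 2 gave 290 calls, leaving out its replicate 1 gave 83, and leaving out Pdcd1hu/- PD-1neg replicate 1 gave 22.

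The interaction tested whether the gates differed to another extent in the genotypes. edgeR called 0 genes (709 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 108, of which 49 were higher and 59 lower. The cell cycle list alone passed, downward (camera adjusted p = 0.00195, adjusted p = 0.971 with an estimated correlation), with 1 of 35 members above 0 and 1 lower when adjusted over the list alone. Cdc27 (3.57), Abca1 (3.19) and Etnk1 (1.73) upward and Thbs2, Rrm1 (-3.70) and Snapc2 (-4.71) downward had the smallest unadjusted p, with an edgeR adjusted p of 1. The difference for Pdcd1 was -2.28 (SE 0.78, edgeR adjusted p = 1), and Kit, Ccr6, Il7r, Cpt1a, Il22 and Il17a also had an adjusted p of 1. Leaving out Pdcd1hu/+ PD-1neg replicate 2 gave 327 calls, and leaving out its replicate 1 gave 14. Across 18862 genes, which are not independent replicates, the gate effects in the genotypes correlated with r = 0.065, and with r = 0.16 over the 7734 genes of 16 CPM or more. Genotype effects in the gates correlated with r = 0.051 and 0.079.

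Etomoxir inhibits the carnitine palmitoyltransferase CPT1, through which long-chain fatty acids enter mitochondria, and the labels set it against vehicle in LTi cells cultured with palmitic acid and carnitine. With etomoxir, the lists of fatty acid oxidation, the TCA cycle and targets of NRF2, of ATF4, of p53 and of the unfolded protein response were higher with camera, and ribosomal protein, mitochondrially encoded and ILC1 or NK marker lists were lower. None of these calls held with an estimated correlation (adjusted p = 0.927) or with fry, and in each list part of the members passed singly. The vehicle arm was 1 sample, so the fit had 1 residual degree of freedom and no difference of that sample from other vehicle samples could enter it. Il17f and Csf2 fell while Il22 and Il17a did not pass. edgeR called 1519 of 16495 genes, 1005 higher and 514 lower. DESeq2 called 1433 and limma-voom 0, and with the vehicle libraries counted as 2 samples edgeR called 5303. Of the 1519 genes, 156 were at 0 in a group, and between the etomoxir libraries themselves 697 genes were at 0 in one and at 20 counts or more in the other.

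Among NRF2 targets, 9 of 20 rose and none fell (camera adjusted p = 0.0172, adjusted p = 0.927 with an estimated correlation). Hmox1, which encodes heme oxygenase, rose by 2.34 on the log2 scale (SE 0.23, edgeR adjusted p = 4.08e-09), from 437 to 2210 ± 381 CPM (SD, n = 2). Pgd (2.04) and Srxn1 (1.56) were next. As a share of counts the NRF2 list was not higher, at 2.56% and 2.84% with etomoxir against 2.83% and 2.71% in the vehicle files. ATF4 targets rose in 8 of 28 members (camera adjusted p = 0.0411, adjusted p = 0.927 with an estimated correlation), led by Trib3 (1.45), Sesn2 (1.37) and Phgdh (0.85). In the unfolded protein response, 8 of 21 rose and 1 fell (camera adjusted p = 0.0197, adjusted p = 0.927 with an estimated correlation), with Dnajb11 (1.49), Pdia4 (1.33) and Creld2 (1.24). Among p53 targets 5 of 18 rose (camera adjusted p = 0.018, adjusted p = 0.927 with an estimated correlation), including Cdkn1a (0.95) and Bbc3 (2.86). Adjusted over the list alone, 10 NRF2 targets were higher and 2 lower, 10 ATF4 targets were higher and 1 lower, 10 members of the unfolded protein response were higher and 1 lower, and 7 p53 targets were higher.

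**Figure D3:**
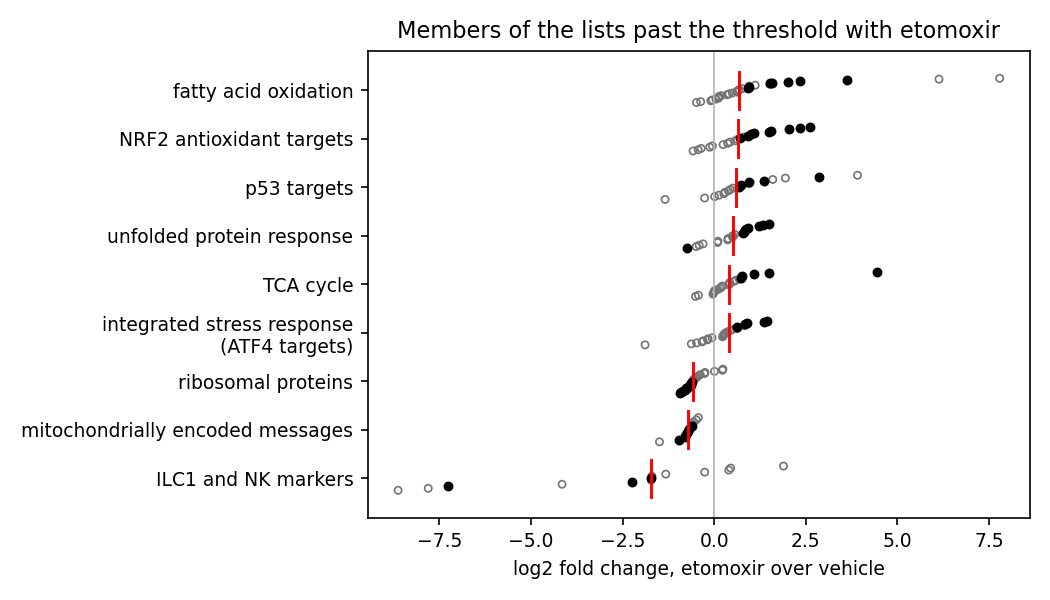
Each point is 1 member of a gene list that passed the set test with etomoxir, at its log2 fold change over vehicle on the horizontal axis; filled points have an edgeR adjusted p under 0.05, open points do not, and a vertical stroke marks the median. The median of the NRF2 targets lies at 0.67 and that of the mitochondrially encoded messages at -0.70.

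Fatty acid oxidation rose with the inhibitor in 7 of 29 members, and 25 lay above 0 (camera adjusted p = 0.00182, adjusted p = 0.927 with an estimated correlation). Acaa2 (2.01, SE 0.40), Hadha (1.59, SE 0.40) and Hsd17b4 (2.35, SE 0.57) led it. Cpt1a, which encodes a form of CPT1, had 4.40 and 12 CPM against 3.76 CPM and did not pass (edgeR adjusted p = 0.534). The TCA cycle rose in 6 of 22 members (camera adjusted p = 0.0197, adjusted p = 0.927 with an estimated correlation), with Pcx (4.44) and Cs (1.08). In glycolysis 6 of 22 members rose, among them Pkm (1.20), Ldha (1.11) and Pfkl (1.67), although the list did not pass (camera adjusted p = 0.215). Nuclear-encoded respiratory chain genes went both ways, with 7 higher and 15 lower of 47 (camera adjusted p = 0.218). Mitochondrially encoded messages fell in 6 of 12 members (camera adjusted p = 0.0176, adjusted p = 0.927 with an estimated correlation), led by mt-Nd4 (-0.97), mt-Nd1 (-0.81) and mt-Co1 (-0.73). Ribosomal protein genes fell in 11 of 23 members (camera adjusted p = 0.0116, adjusted p = 0.927 with an estimated correlation), and the most abundant, Rps19, did not pass (-0.50, edgeR adjusted p = 0.117). Adjusted over the list alone, 17 ribosomal protein genes were lower.

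Effector cytokines did not pass as a list (camera adjusted p = 0.889), but Il17f fell by 0.74 (SE 0.19, edgeR adjusted p = 0.00805) and Csf2 fell by 0.77 (SE 0.19, edgeR adjusted p = 0.00529). Il22, at 86500 ± 1870 CPM against 110000 CPM, and Il17a (-0.77) did not pass, with edgeR adjusted p of 0.276 and 0.087. Early response genes went both ways, 5 higher and 3 lower of 23, with Junb (0.94), Nfkbid (1.08) and Ier2 (0.92) higher. ILC1 and NK markers fell in 3 of 13 members (camera adjusted p = 0.0251, adjusted p = 0.927 with an estimated correlation), and Ifng, the most abundant, did not pass (edgeR adjusted p = 0.665). Pdcd1 rose by 1.5 (SE 0.25, edgeR adjusted p = 8.04e-05). Kit, Ccr6 and Il7r did not pass, with edgeR adjusted p between 0.449 and 0.814.

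The largest increases with etomoxir by the rule were from near 0 in the vehicle sample. Abhd8 was at 0 with vehicle and at least 296-fold higher, and Zfp764 had 27.0 CPM against 0.0587 CPM. Spg7, which encodes the mitochondrial protease paraplegin, rose by 6.04 (SE 0.61, edgeR adjusted p = 6.93e-09), and Fech (7.01), Ppp2r5d (6.70) and Lrrc41 (4.06) also rose. The largest decreases were those of Xcl1 (-7.26, SE 0.66, edgeR adjusted p = 1.82e-09), Gzmc (-2.23), Taf15 (-2.14), Ifitm3 (-1.91), Zfas1 (-1.89) and the Y-linked Uty (-1.88, edgeR adjusted p = 0.0193). Uty did not pass with DESeq2 (adjusted p = 0.0564). Genes that rose had a higher GC content than genes that fell, with medians of 53.1% over 695 genes and 44.8% over 396 genes of 16 CPM or more.

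Palmitic acid, a long-chain fatty acid, was added to LTi cells to find the genes it changes. The count columns of its libraries are named iL per the file headers and P per the labels, and all values below rest on the labels. Plin2, which encodes a protein that coats lipid droplets, rose, and 36 genes fell. Fatty acid oxidation, glycolysis, effector cytokine and early response lists did not pass. edgeR called 37 of 13811 genes, 1 higher and 36 lower, with 836 at an unadjusted p under 0.05. limma-voom called 44, DESeq2 128 (22 higher, 106 lower), and without a filter on low counts edgeR called 144. A filter at a mean CPM of 10 gave 87. Plin2 (ENSMUSG00000028494, protein coding, chromosome 4, 86648386 to 86670060) rose by 0.85 (SE 0.08, edgeR adjusted p = 0.00492), from 399 ± 10.1 to 721 ± 49.0 CPM (SD, n = 2). It was 1 of 17 members higher in the list of fatty acid uptake and PPAR targets, which did not pass (camera adjusted p = 0.723, with a mean above 0 and a median below).

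The largest decreases with palmitic acid were those of Alyref, an mRNA export factor, Dapk3, Otulin, Tmem243, Snx20 and Dexi. Alyref fell by 3.34 (SE 0.16, edgeR adjusted p = 0.00025), from 128 ± 12.6 to 12.6 ± 0.335 CPM (SD, n = 2). Dapk3 fell by 2.94 (SE 0.27), Otulin fell by 2.78 (SE 0.14) and Tmem243 fell by 2.49 (SE 0.18), with edgeR adjusted p of 0.0031, 0.00025 and 0.00141. Snx20 fell by 2.43 and Dexi fell by 2.38. The first 200 bases of the longest transcripts of the 36 had a median GC content of 75.8%, against 62.5% in 6950 other genes of 16 CPM or more. Mboat7 (0.92) and Neat1 (0.45) were the next increases and did not pass (edgeR adjusted p = 0.346).

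**Figure D4:**
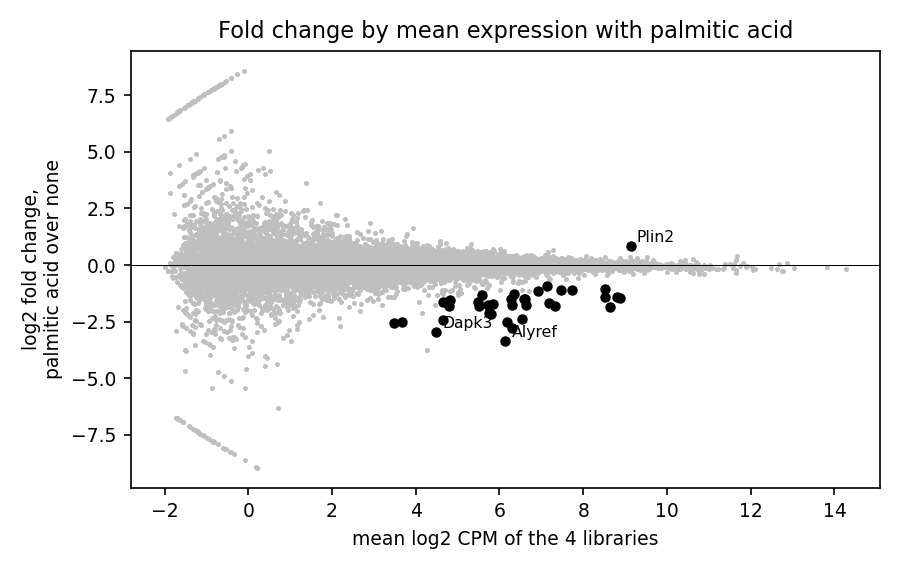
The horizontal axis gives the mean log2 CPM of a gene over the 4 libraries, and the vertical axis the log2 fold change with palmitic acid; black points are the 37 genes called by edgeR and grey points the other genes tested. Plin2 lies at 0.85 and Alyref at -3.34.

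Genes of fatty acid oxidation did not pass with palmitic acid (camera adjusted p = 0.444, 0 of 30 called). Cpt1a, at 43.8 ± 4.39 against 29.1 ± 6.32 CPM (SD, n = 2), was 0.59 higher (SE 0.22, edgeR adjusted p = 0.764), and Ehhadh (2.40) and Crat (-0.62) were its neighbours in the list. Mitochondrially encoded messages fell as a list (camera adjusted p = 0.0175, adjusted p = 0.914 with an estimated correlation), with 0 of 13 members above 0. They took 1.08% and 1.04% of counts against 1.32% and 1.08%, so that 1 library without palmitic acid stood apart. None of these was called singly over all genes, 1 was lower when adjusted over the list alone, and mt-Nd5 (-0.30), mt-Cytb (-0.34) and mt-Nd6 (-0.27) led. Among effector cytokines, Ltb (-0.25), Areg (1.62) and Il22 (-0.17) did not pass, nor did Egr1 (1.14), Egr2 (-2.68) and Nfkbiz (0.34) in the early response or Aldoc, Slc16a3 and Pkm in glycolysis. For effector cytokines the mean was above 0 and the median and camera direction below, and for the early response the reverse held. Pdcd1 (0.30, edgeR adjusted p = 0.927), Kit, Ccr6 and Il7r did not pass.

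Across 12788 genes tested in both experiments, fold changes with etomoxir and with palmitic acid correlated with r = 0.032, and with r = 0.087 over 5756 genes of 16 CPM or more. Of the genes called in both, 1 was higher in both, 1 lower in both and 6 opposite, where independent lists would give 0.0774, 1.31 and 2.82.

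Single cells were used to relate activation to metabolism in ILC3, and 11 clusters of 8084 cells gave 4 classes. ILC2-like cells numbered 3107 (38.4%), NCR+ ILC3-like cells 2943 (36.4%), LTi-like cells 1297 (16%, 95% interval 15.3% to 16.9%) and ILC1/NK-like cells 513 (6.35%). A cluster of 224 cells (2.77%), led by Amigo2, Atp1b2 and Hcar2, stayed without a name. The names rest on rebuilt clusters, and heat-shock genes (Hspa1a, Hspa1b, Dnajb1) led cluster 8 and the interferon-stimulated Ifit3 cluster 0, both NCR+ ILC3-like. Ccr6 had 181 CPM of UMIs in LTi-like and 25.3 in NCR+ ILC3-like cells, and Ncr1 90.6 and 349. Both genes were among the markers that gave the names, so these levels do not check them.

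Pdcd1 was highest in LTi-like cells, at 35.9 CPM of UMIs (95% interval 29.6 to 43.2, 113 UMIs). NCR+ ILC3-like cells had 2.21 (1.33 to 3.46), ILC2-like cells 12.6 (10.3 to 15.2) and ILC1/NK-like cells 2.92 (0.795 to 7.47). A Pdcd1 UMI was seen in 5.55% of LTi-like and 0.476% of NCR+ ILC3-like cells, at medians of 2267 and 2897 UMIs per cell. After thinning to 1500 UMIs the shares were 4.03% and 0.256%, with 155 and 211 shallower cells left out. Both LTi-like clusters carried it, at 42.7 CPM in cluster 1 and 29 in cluster 10 (21.2 to 38.8). ILC2-like cluster 6 overlapped with cluster 10, at 19.8 CPM (15.2 to 25.3). A Pdcd1 UMI was seen in 4.28% of the cells of cluster 6 and 4.5% of those of cluster 10. The other ILC2-like clusters had 6.01 to 9.89 CPM, and 2.77% of all ILC2-like cells had a Pdcd1 UMI.

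Cytokine messages differed between the ILC3 classes and within them. Il22 had 4940 CPM of UMIs in LTi-like cells (8050 in cluster 1 and 1750 in cluster 10) and 1540 in NCR+ ILC3-like cells (1060, 1670 and 2260 in clusters 0, 2 and 8), so that cluster 10 lay below cluster 8, against 55.9 in ILC2-like cells. Il17a (16.5 against 3.38), Il17f (77.2 against 10.4) and Lta (82.6 against 39.0) were also higher in LTi-like cells. Il17f and Lta were markers for naming LTi clusters, so their differences were partly set by the naming. Csf2, Tnf (324 against 682), Il2 (16.2 against 38.4) and Ifng (13.4 against 111) were higher in NCR+ ILC3-like cells. Ifng was a marker for naming NCR+ ILC3 clusters, so the same holds for it. Il22 was such a marker too, yet it was higher in LTi-like cells. Il17a was highest in cluster 9, an ILC2-like cluster of 350 cells with Pcsk1, Irf4 and Il13 among its leading genes, at 267 CPM of UMIs and in 15.4% of its cells. MHC class II messages took 0.385% of UMIs in LTi-like and 0.0266% in NCR+ ILC3-like cells, with Cd74 at 1600 and 27.1 and H2-Aa at 799 and 9.67 CPM.

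**Figure D5:**
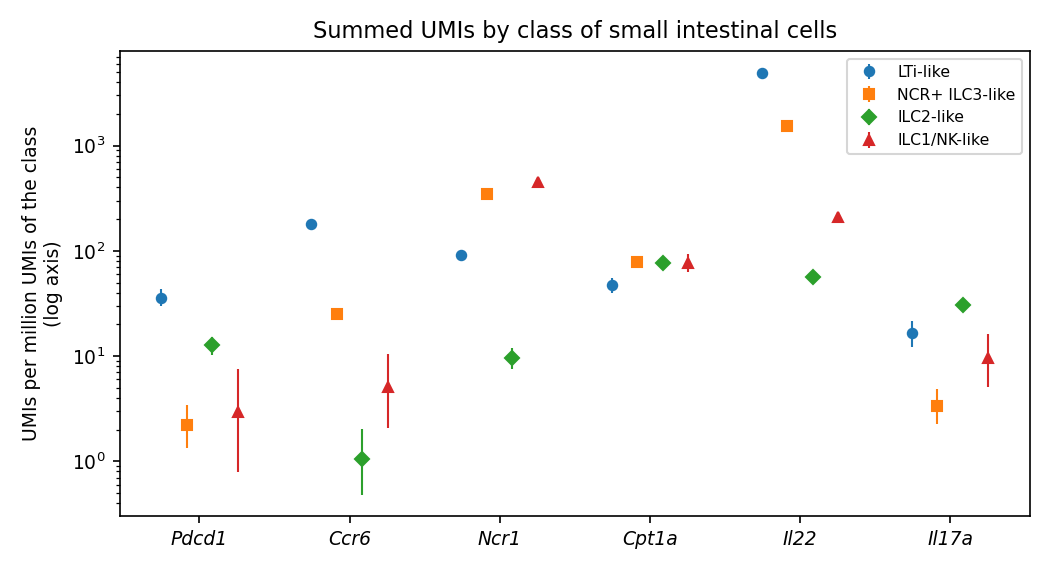
Points give the UMIs of a gene as CPM of the UMIs of a class on a log axis, for the genes on the horizontal axis, and bars are exact 95% Poisson intervals that cover counting error only. Pdcd1 lies at 35.9 in LTi-like cells and at 2.21 in NCR+ ILC3-like cells, and Cpt1a at 47.0 and 79.1.

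Metabolic messages were compared between the ILC3 classes next. Cpt1a had 47.0 CPM of UMIs (39.8 to 55.3) in LTi-like and 79.1 (73.2 to 85.2) in NCR+ ILC3-like cells, a ratio under the 2-fold limit. Of 29 fatty acid oxidation genes, 1 passed the size limit, Acaa2, at 21.6 against 50.9. The list of fatty acid uptake and PPAR targets took 0.164% of UMIs (0.16% to 0.169%) in LTi-like and 0.336% (0.332% to 0.34%) in NCR+ ILC3-like cells, of which Ucp2 alone made up 42.5% and 68.5%, and 18 of 21 members passed in neither class. In it, Ucp2 (698 against 2300), Ucp3 (7.95 against 38.4) and Ppargc1b (4.45 against 10.9) were lower in LTi-like cells. In glycolysis 1 of 22 members, Slc16a1, was higher in LTi-like cells. Hypoxia targets took 0.168% of UMIs in LTi-like cells, led by Vegfa, and 0.0921% in NCR+ ILC3-like cells, led by Ero1a. Early response genes took 4.60% and 4.93%, and of 25 members Egr3 and Dusp2 were higher in NCR+ ILC3-like cells.

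Cell by cell, the early response share was set against each metabolic list over 3874 thinned ILC3-like cells, with 366 shallower cells left out. Spearman's rho over cells of 1 sample, which are not replicates, was -0.151 for nuclear-encoded respiratory chain genes (percentile 4.1 of matched random lists), -0.094 for the TCA cycle (6.5) and -0.1 for fatty acid oxidation (10.3). It was -0.089 for fatty acid uptake and PPAR targets (8.0), -0.059 for fatty acid synthesis (29.4), -0.060 for cholesterol synthesis (35.7) and -0.018 for cholesterol efflux (77.3). Glycolysis had a rho of -0.006 (78.3) and mitochondrially encoded messages 0.043 (37.6). All 9 values lay inside the central 95% of random lists. The respiratory chain value left that range in LTi-like cells alone (-0.193, percentile 1.7, random lists -0.186 to 0.015) and without thinning (-0.196, percentile 2.2, random lists -0.195 to -0.006).

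LTi-like cells with a Pdcd1 UMI, 72 in number, had 3.86% of their UMIs in early response genes (3.78% to 3.95%). The 1225 LTi-like cells without one had 4.66% (4.63% to 4.68%). Effector cytokines took 0.757% and 0.655%, glycolysis 0.318% and 0.281%, fatty acid oxidation 0.122% in both, and mitochondrially encoded messages 2.02% and 2.23%. The TCA cycle took 0.177% (0.159% to 0.196%) and 0.149% (0.144% to 0.153%), and nuclear-encoded respiratory chain genes 0.691% (0.656% to 0.728%) and 0.645% (0.636% to 0.654%). The median depth was 2609 UMIs with and 2253 without a Pdcd1 UMI.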

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

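Of the tests below, those of GC content in the palmitic acid genes, of the separate vehicle libraries, of the 4 libraries with least Igkc, of heat-shock genes, of cells with a Pdcd1 UMI of the splits for any list and of the splits for called genes were chosen only after the result was seen.

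The cell cycle list was lower in the interaction of genotype and gate (camera adjusted p = 0.00195, and 0.971 with an estimated correlation), which marked it as a difference between groups not asked for by the series. Pdcd1hu/- PD-1neg replicate 1 held most of these messages, with Top2a at 79.3 CPM.

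Early response genes were lower as a list in PD-1high cells averaged over genotypes with camera, a call that did not hold with an estimated correlation (adjusted p = 0.526). Of 35 splits of the 8 libraries, 1 gave this list a camera p as small, the real split at 1.1e-05 against 3.29e-05 for the next, but 11 others gave it one under 0.05, and in 24 of 35 some list had a p as small, down to 3.25e-16, so chance cannot be excluded for a list chosen among all. The tables argue against plasma cell RNA, since the median was -0.98 (-1.41 to -0.29) in the 4 libraries with least Igkc and -0.39 (-0.76 to -0.22) over all 8 with the Jchain level as a covariate, though both intervals reach past the bound of -0.3 set beforehand for the covariate and clear only the bound of -0.1 set afterwards for the 4 libraries. Handling that differed between the gates could account for the pattern, since the heat-shock list had a median of -0.63 (-0.69 to -0.49). RNA of other cells stays open as untested. In the 4 libraries stromal markers took 0.235% and 0.239% of counts in PD-1high against 0.0134% and 0.0188%, and erythroid markers 0.815% and 0.496% against 0.00434% and 0.000583%. In the remaining libraries stromal markers took 0.16% and 0.0225% in PD-1high against 0.43% and 0.0574% in PD-1neg. Erythroid markers took 0.00372% and 0.303% there against 0.0739% and 0.00545%, so neither list kept its direction throughout. Lower early response messages in LTi cells that carry Pdcd1 could account for it too. Single LTi-like cells with a Pdcd1 UMI, from the small intestine and not the colon, had 0.828 times the share of the others. This was 1 of 6 among 10 lists whose intervals lay apart in those cells. Heat-shock genes took 0.94% and 0.945% there and did not go along. Glycolysis (0.318% against 0.281%), the TCA cycle (0.177% against 0.149%) and mitochondrially encoded messages (2.02% against 2.23%) went opposite to the averaged gates. Nuclear-encoded respiratory chain genes (0.691% against 0.645%) went the same way. A difference between the gated cells stays open as untested.

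Targets of NRF2, ATF4 and the unfolded protein response were higher with etomoxir with camera, with a median of 0.52 (0.34 to 0.69) over 68 members, none of these lists held with an estimated correlation (adjusted p = 0.927), and NRF2 targets took 2.56% and 2.84% of counts against 2.83% and 2.71% with vehicle. GC content or transcript length cannot be told apart as a cause, since the median after removing both trends was 0.19 (0.08 to 0.46). By list, the medians after removal were 0.48 (0.18 to 0.96) for NRF2, 0.07 (-0.33 to 0.28) for ATF4 and 0.52 (0.08 to 0.65) for the unfolded protein response. A difference of the vehicle library unrelated to etomoxir cannot be told apart either, since the vehicle files held 1 separate library. An effect of etomoxir stays open, and no further vehicle library was available.

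The 36 genes lower with palmitic acid had a median of -1.69 (-1.82 to -1.49). GC content alone is argued against, since 338 genes of like GC content had a median of 0.00 (-0.03 to 0.03). Near-identical copies were as frequent as in matched genes, at 19.4% (8.2% to 36%) against 21.7% (17.5% to 26.3%), which argues against shared reads. Uneven recovery of these transcripts between libraries stays open. Their mean pairwise correlation over the 8 colonic libraries, 0.089, lay at percentile 99.8 of random sets, the outcome set beforehand for uneven recovery. The test cannot decide it, since genes regulated together would correlate as well. The colonic libraries came from another tissue and experiment, and the random sets were matched on mean expression but not on GC content. An effect of palmitic acid stays open as untested in other libraries.

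For genes called between the gates averaged over genotypes, 4 of 35 splits called as many, the real split 1 and the highest other 5, so chance cannot be excluded.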

How the results depend on the processing

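The vehicle sum behind the 1519 etomoxir calls, the fits with a Jchain covariate, without the 4 libraries richest in Igkc and with a crossed block, and the repeated correlations of fold changes were chosen only after the data were seen. The fit with vehicles counted as 2 was the planned one, and the other alternatives were chosen before the data were examined. Among values for named genes, 2986 kept their side of the threshold, 184 passed it only under an alternative, and 45 missed it only there, 41 of them with limma-voom. Of values past the threshold in either fit, 0 changed sign. Changes of sign in values past it in neither fit were not counted, so the 2986 may hold some. The cause was not tested except where fewer samples or genes were fitted.

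Without a filter on low counts, calls were 42 and 63 for the gates in Pdcd1hu/+ and Pdcd1hu/-, 5 and 45 for genotype in PD-1high and PD-1neg, 15 for the interaction, 151 for the averaged gates and 144 for palmitic acid. With a mean CPM of 10 or more they were 0 for the averaged gates and 87 for palmitic acid, and the gate effects correlated with r = 0.125. DESeq2 called 120, 203, 100, 156, 108, 301 and 128 in the same order, and limma-voom 0 with etomoxir, where edgeR had 3489 at an unadjusted p under 0.05 and 1519 called. Vehicles counted as 2 gave 5303.

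Whether the replicate numbers pair the samples is not stated in the labels. Deviations from group means correlated with r = 0.069 and 0.108 between the gates in Pdcd1hu/+ and Pdcd1hu/-. Between the genotypes r was -0.034 in PD-1high and -0.218 in PD-1neg cells, and between the palmitic acid groups 0.016. With 2 libraries per group these values cannot decide it. A replicate block gave 4 and 1 for the gates, 1 for the interaction, 6 for the averaged gates and 44 for palmitic acid, and in the list test 3 lists for the gates in Pdcd1hu/+ and 2 for the interaction. A crossed block gave 1 call for genotype in PD-1neg cells. No paired analysis was possible for etomoxir, because its vehicle libraries counted as 1 sample. The Jchain covariate gave 2, 1, 2 and 0 for the gates, genotype in PD-1neg and the averaged gates. Without the 4 Igkc-rich libraries, 22 genes and 5 lists passed for the averaged gates. An estimated correlation left 0 lists in each of 8 comparisons, as did fry, against 1, 6, 1, 4, 1, 10, 9 and 1. The power of either of these tests at so few residual degrees of freedom was not simulated. With the preset correlation, every other even split of the colonic libraries gave list calls too. The lists therefore stay undecided. Library totals gave 3 lists for genotype in PD-1high.

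Leaving out single libraries gave 0 to 449 and 1 to 19 for the gates, 0 to 1 and 2 to 290 for genotype, 0 to 327 for the interaction, 2 to 595 for the averaged gates and 27 to 35 for palmitic acid. For etomoxir, 1320 to 1332 came from leaving out either vehicle file, which stand for the same sample, and say nothing about stability. Without Pdcd1hu/+ PD-1neg replicate 2 the counts were 449, 290, 327 and 595, without its replicate 1 they were 38, 83, 14 and 93, and without Pdcd1hu/- PD-1neg replicate 1 they were 19, 22, 4 and 67 (own gate, genotype, interaction, averaged). Without Pdcd1hu/- PD-1neg replicate 2 they were 3, 2, 2 and 9. For the averaged gates, PD-1high replicates 1 and 2 gave 2 and 9 in Pdcd1hu/+ and 27 and 12 in Pdcd1hu/-. Leaving out an etomoxir library left 1 against 1 and gave no value.

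In single cells, LTi-like cells were 13.8% and 13.7% at resolutions of 0.5 and 2, 13.9% with 500 genes and 14.9% with doublets kept. NCR+ ILC3-like cells were 41.2% and 33.9% at these resolutions and 39.4% with 500 genes, and ILC1/NK-like cells 3.09% at a resolution of 2, 5.35% with 500 genes and 7.08% with doublets kept. Without thinning, rho of early response and respiratory chain was -0.196. In LTi-like cells alone it was -0.193, with -0.076 for fatty acid oxidation, -0.024 for cholesterol synthesis, -0.106 for glycolysis and -0.041 for the TCA cycle. In NCR+ ILC3-like cells alone it was -0.027 for fatty acid and -0.031 for cholesterol synthesis.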
